A study of Homo sapiens with 10 samples.

How the data were processed

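RNA from MCF7 cells, an established estrogen receptor positive breast cancer line, was profiled in 10 libraries, 2 biological replicates in each of 5 stable lines. The lines carried an empty vector, a fragment called 1K, a fragment called 2K, a scrambled shRNA (shScr) or a knockdown of TRIM28 (shTRIM28). Per the labels, the libraries were stranded total RNA libraries read from both ends on an Illumina instrument. The deposited tables hold raw counts of read pairs per Ensembl gene ID, 1 table per library, and the values were neither normalized nor filtered by the authors as far as the tables show. Each table lists 60572 genes and no entry that names no gene, and all values are whole numbers. The submitters' processing notes name the hg38 build, TopHat2 2.0.10 and HTSeq 0.6.0, with no role or order. The annotation release, the strand setting and the treatment of reads that fit several genes are not stated. Gene symbols came from a gene name table that matched 60258 of the IDs without their version, and positions and biotypes from GENCODE 29 on GRCh38, which matched 58465. The 13 mitochondrially encoded protein genes are not in the tables, so their share could not be given. Counts are not independent molecules where fragments were amplified, so every counting interval covers counting error only.

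The choices in this paragraph and the gene lists were fixed before the data were examined. Libraries were grouped by their labels. Counts were normalized by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood model, using 1 fit of 5 group means with 5 residual degrees of freedom. The filterByExpr defaults (minimum count 10, minimum total 15) left 19190 genes. The quasi-likelihood F test, two-sided, was made for 7 comparisons: 1K, 2K and shScr each against vector, shTRIM28 against shScr, 2K against 1K, and the shTRIM28 effect minus the 1K or the 2K effect. P-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. Levels are TMM-scaled CPM (counts scaled to library size) with the SD of 2 libraries. The SE of a log2 fold change is its size divided by the square root of F. Each p-value measures the spread between these libraries. The labels do not say whether the replicates of a group are separate transductions, clones or passages of the same stable line, so a difference between lines that is not caused by the construct cannot be separated from its effect.

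Of 24 gene lists fixed before the data were examined, 23 had measured members and were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the 23 lists within a comparison. An estimated correlation and fry served as alternatives. The lists cover corepressor and chromatin subunits, zinc finger, protocadherin and histone families, cell type markers, and genes of hormone, interferon, p53, stress and metabolic responses, all named with the results. Few genes are in more than 1 list: 3 are both estrogen receptor targets and luminal markers, 2 are both estrogen receptor targets and immediate early genes, and 7 other pairs of lists share 1 gene each. Counts of members passing are given over all genes tested and adjusted over the list alone. Names follow a rule. TRIM28 and ZNF568, the human counterpart of the mouse ZFP568 that the series title names, come first in every library. For 1K against vector, 2K against vector and shTRIM28 against shScr, the rule then takes the 10 higher and 10 lower protein-coding genes with the greatest log2 fold change among those called, with a mean of at least 1 CPM and no overlap between the groups. For the other 4 comparisons it takes 5 and 5, without the overlap condition for differences of effects. From each list it takes up to 4 called members, or the 2 most abundant where none was called. It also takes 10 genes called in the same direction in the 3 main comparisons, and 5 called in opposite directions by the knockdown and both fragments.

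Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no low-count filter beyond 1 count (40795 genes tested), at least 50 counts in 2 libraries (14282 genes), the replicate number as a block, only the groups of a comparison in the fit, glmTreat against a 1.2-fold change, and each library left out in turn. A lone library left in a group was assumed to vary like the other groups. A correction for GC content and transcript length, the other control line (vector exchanged with shScr), an exchange of both control lines in the differences of effects, and list tests on these differences were added after the data had been seen. The GC correction subtracted, per library, a loess trend (span 0.5) of log2 CPM (offset 0.5) on both properties.

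The procedure was tested on simulated counts with the fitted means and dispersions, in which 67, 67 and 66 of 19190 genes were changed 1.5-fold, 2-fold and 4-fold. It recovered 56.7%, 80.6% and 86.4% of them for 1K against vector. For 2K it recovered 46.3%, 71.6% and 92.4%, and for the knockdown 58.2%, 76.1% and 95.5%. False calls were 10.8%, 7.89% and 7.27% of calls with gene-specific dispersions, and 3.87%, 5.7% and 3.23% with dispersions taken from the trend. Overlaps between comparisons were described with Fisher's exact test, and overlaps of 1K and 2K and correlations also with 20 simulated draws of unchanged groups against the same vector libraries. Taking as many genes by p in each draw as were called in the data was added after the data had been seen. Where a group held 1 to 3 counts, a ratio with its 95% counting interval (exact Clopper-Pearson) is given, and a group at 0 was set to a floor of 3 counts over the group. This also holds where a library left out leaves so few.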

Results

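Gene expression was measured by RNA sequencing in 10 libraries of MCF7, an estrogen receptor positive breast cancer cell line, in 5 groups of 2 biological replicates. The groups were stable lines with an empty vector, with a fragment called 1K, with a fragment called 2K, with a scrambled shRNA (shScr) and with a knockdown of TRIM28 (shTRIM28). The series text speaks of expression of a KRAB domain, the part of many zinc finger proteins that binds the corepressor TRIM28, and the labels do not say what 1K and 2K stand for. The vector libraries held 37204060 and 32939866 counts, the 1K libraries 33822804 and 35689790, and the 2K libraries 36031668 and 32912150. The shScr libraries held 41008938 and 35576870 counts and the shTRIM28 libraries 36446460 and 41219943. Between 27469 and 32512 genes had at least 1 count in a library. The highest number was in vector replicate 2, where 12469 genes had 1 to 5 counts against 7964 to 10417 in the other libraries.

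TRIM28, the corepressor recruited by KRAB zinc finger proteins (ENSG00000130726.12, GRCh38 chromosome 19, 58544091 to 58550722), was at 482 and 440 CPM in the vector libraries. It was at 531 and 528.1 CPM in the 1K libraries, 572 and 565 in the 2K libraries, 502 and 486 in the shScr libraries, and 378 and 358 in the shTRIM28 libraries. Its log2 fold change in the knockdown against shScr was -0.43 (SE 0.05, adjusted p = 2.86e-06), with both knockdown libraries below all 8 others. TRIM28 rose in the 2K line against vector by 0.30 on the log2 scale (SE 0.05, adjusted p = 6.8e-05), and this call was lost against a 1.2-fold change. In the 1K line the log2 fold change was 0.20 (SE 0.05, adjusted p = 0.0379), a call that was lost without vector replicate 2 (0.14), 1K replicate 1 (0.20) or 1K replicate 2 (0.20). It was also lost with a GC and length correction (0.05), with a stricter low-count filter (0.18), with only these 2 groups in the fit (0.20) and against a 1.2-fold change. ZNF568, a KRAB zinc finger repressor (ENSG00000198453.13, chromosome 19, 36916329 to 36998700), was at 4.17 and 5.17 CPM in the vector libraries and at 7.85 and 8.11 in the shScr libraries. Its levels were 5.96 and 5.84 CPM in the 1K libraries, 6.84 and 6.25 in the 2K libraries, and 5.05 and 5.35 in the shTRIM28 libraries. ZNF568 rose in 2K against vector (log2 fold change 0.49, SE 0.132, adjusted p = 0.00518) and fell in the knockdown against shScr (-0.62, SE 0.123, adjusted p = 0.000757), and the value in 1K was 0.34 (SE 0.133, adjusted p = 0.194). The 2K call was lost without vector replicate 1 (0.34) and without 2K replicate 1 (0.43), and the 1K value was 0.19 without vector replicate 1. Against the other control line, chosen after the data were seen, the ZNF568 values changed sign to -0.44 in 1K, -0.28 in 2K and 0.16 in the knockdown.

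**Figure D1:**
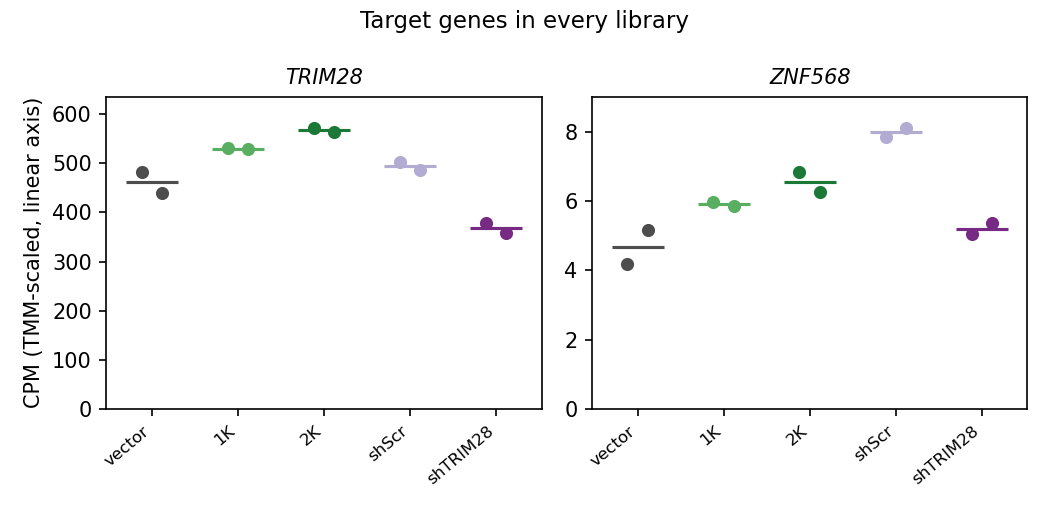
TMM-scaled CPM of TRIM28 and ZNF568 in each of the 10 libraries on linear axes from 0, with points for libraries and a bar at the mean of each group. The shTRIM28 libraries, at 378 and 358 CPM of TRIM28, lie below the other 8, and the shScr libraries hold the highest ZNF568 levels, 7.85 and 8.11 CPM.

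The 1K line was compared with its vector to ask what the fragment changes in these cells. ZNF486 (ENSG00000256229.8, chromosome 19, 20167228 to 20200490) went from 2.95 ± 0.000879 to 10.3 ± 0.612 CPM (SD, n = 2 each), a log2 fold change of 1.81 (SE 0.118, adjusted p = 4.02e-08). ZNF681 (ENSG00000196172.9, chromosome 19, 23739195 to 23758891) went from 11.9 ± 0.0538 to 25.9 ± 0.544 CPM (log2 fold change 1.12, SE 0.076, adjusted p = 4.02e-08). COL3A1, the type III collagen chain (ENSG00000168542.14, chromosome 2, 188974320 to 189012746), fell from 7.54 ± 0.222 to 2.88 ± 0.662 CPM (log2 fold change -1.38, SE 0.145, adjusted p = 2.04e-05). The other genes named as higher were TAS1R3, a taste receptor subunit (1.77), ZNF90 (1.75), GRPR, the gastrin-releasing peptide receptor (1.74), ZNF563 (1.68), ZNF888 (1.49), the transcription factor SIM1 (1.14), the receptor kinase KIT (1.14) and the pregnancy-specific glycoprotein PSG9 (1.10). Those named as lower were the kallikrein proteases KLK5 (-1.26) and KLK6 (-0.91), PSG5 (-1.15), the collectin COLEC10 (-1.09), the exchange factor DOCK10 (-1.07), SERHL2 (-1.04), the sulfotransferase SULT1B1 (-1.02), the collagenase MMP13 (-1.0) and RASGRP1, an activator of Ras (-0.91). ZNF486, ZNF90, ZNF888, PSG9, PSG5 and SERHL2 have close relatives in sequence, so reads shared between paralogs leave their exact values uncertain.

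In all, 481 of 19190 genes were called between 1K and vector, 298 higher and 183 lower, of which 33 and 24 changed at least 2-fold. Against a 1.2-fold change 73 were called, with only these 2 groups in the fit 138, and with no low-count filter 1117. Of the 20 genes named, 8 lost their call without a library. Without vector replicate 1, the values were 0.67 for SIM1, -0.80 for KLK5 and -0.73 for MMP13, and without vector replicate 2 they were -1.06 for PSG5 and -0.70 for SULT1B1, while SIM1 kept its call at 1.76. Without 1K replicate 1 the calls of SIM1 (1.11), KIT (0.93), KLK5 (-1.20), PSG5 (-1.06), SERHL2 (-0.76), SULT1B1 (-1.09), MMP13 (-1.0) and KLK6 (-0.83) were lost, and without 1K replicate 2 those of SIM1 (1.17), PSG5 (-1.24), SULT1B1 (-0.96), MMP13 (-1.01) and KLK6 (-0.99). The calls of KLK5 and SULT1B1 were lost with DESeq2, that of SULT1B1 with the GC and length correction, and that of KLK6 with a replicate block. SIM1, KIT, KLK5, SERHL2 and SULT1B1 lost theirs with only these 2 groups in the fit, and SIM1, KLK5, KLK6, PSG5, SERHL2, SULT1B1 and MMP13 theirs against a 1.2-fold change. Against the shScr line, chosen after the data were seen, 8 of the 20 were on the other side of 0: SIM1 (-2.28), KIT (-1.38), ZNF888 (-0.14), KLK5 (1.47), COLEC10 (1.48), RASGRP1 (1.14), KLK6 (0.92) and MMP13, which had 1 count in shScr. ZNF90 (0.091), PSG5 (-0.044) and SULT1B1 (-0.24) lost their calls there.

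Among the gene lists, the KRAB zinc finger genes stood out in 1K: 47 of 272 measured members rose and the other 225 did not pass the test, and adjusted over the list alone 81 rose and 1 fell. Examples were ZNF441 (log2 fold change 2.00), ZNF69 (1.82), ZNF486 (1.81) and ZNF90 (1.75), and the list was called higher (adjusted p = 4.8e-22, and adjusted p = 0.0236 with an estimated correlation). Interferon-stimulated genes were called higher (adjusted p = 9.41e-05, and adjusted p = 0.0799 with an estimated correlation). Of 45 members 4 rose, IFI27 (0.55), IRF7 (0.38), IFI6 (0.38) and LGALS3BP (0.27), or 10 adjusted over the list alone, and 2 rose without vector replicate 2, 1 without 1K replicate 1 and 2 without 1K replicate 2. Cholesterol synthesis genes were called higher (adjusted p = 3.54e-06, and adjusted p = 0.579 with an estimated correlation). Of 24 members 3 rose, STARD4 (0.53), MVD (0.26) and SQLE (0.25), or 6 adjusted over the list alone, and 1 rose without 1K replicate 1 and 6 without 1K replicate 2. Estrogen receptor targets were called higher (adjusted p = 0.000875, and adjusted p = 0.708 with an estimated correlation). Of 38 members 4 rose, among them PDZK1 (0.75), RERG (0.63) and SIAH2 (0.24), and 1 fell, IGF1R (-0.23), or 5 and 1 adjusted over the list alone, and 2 rose without 1K replicate 1 and 7 without 1K replicate 2. Luminal markers were called higher (adjusted p = 0.00598, and adjusted p = 0.674 with an estimated correlation), with AGR3 (0.94) the 1 of 17 that rose, or 4 adjusted over the list alone. Basal and myoepithelial markers were called lower as a list (adjusted p = 0.0281, and adjusted p = 0.579 with an estimated correlation), although the 1 of 19 members that passed, LAMA3, rose (0.40), and adjusted over the list alone 2 rose and 4 fell. Clustered protocadherins were called lower as a list (adjusted p = 0.000875, and adjusted p = 0.625 with an estimated correlation) with a median of -0.22, while edgeR and DESeq2 each called 0 of the 48 members and 13 had an unadjusted p under 0.05. The most abundant were PCDHB16 (-0.08, adjusted p = 0.688) and PCDHA11 (-0.13, adjusted p = 0.563).

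The other 16 lists were not called in 1K. Counting the protocadherins, 9 lists with 212 members had 0 calls by edgeR and 40 members with an unadjusted p under 0.05. The others were the mesenchymal, leukocyte and endothelial, p53 target, imprinted, cancer-testis, unfolded protein and stress response, hypoxia and glycolysis, and immediate early genes. DESeq2 called 1 imprinted gene lower and 1 hypoxia gene higher. Adjusted over the list alone, 2 p53 targets were higher and 2 lower, 1 imprinted gene was lower and 1 immediate early gene was higher. The TRIM28 corepressor list had TRIM28 higher and CHD3 (-0.19) lower among 23, the same adjusted over the list alone. PRC2 and SWI/SNF subunits had ARID1A (-0.24) lower among 25, fibroblast and stromal markers had COL3A1 lower among 9, autophagy genes had ATG101 (0.25) higher among 35, and neuronal genes had MAP2 (-0.36) lower among 10, each also adjusted over the list alone. Of 30 epithelial junction genes 3 rose and 1 fell (4 and 3 adjusted over the list alone), among them OVOL2 (0.60) and DSC2 (-0.40), and 0 rose without vector replicate 2 and 1 without 1K replicate 1. Of 48 proliferation genes CDT1 (0.37) and CDC20 (0.29) rose (2 higher and 1 lower adjusted over the list alone), and H3C2 (0.18) was the 1 of 42 histone genes called, which it was not over the list alone. Median and mean differed in sign for mesenchymal (-0.00954 and 0.0211), fibroblast (-0.0605 and 0.0101), leukocyte (0.174 and -0.0238) and hypoxia genes (0.00402 and -0.0108), none of them called, with the test pointing up for the first and down for the other 3. Against the shScr line 8639 genes were called, 45 KRAB genes were higher and 93 lower (adjusted p = 0.0582, and adjusted p = 0.409 with an estimated correlation). Of the basal markers 13 were higher and 4 lower there (adjusted p = 2.67e-05, and adjusted p = 0.302 with an estimated correlation), and of the luminal markers 3 were higher and 7 lower (adjusted p = 0.0218, and adjusted p = 0.531 with an estimated correlation). Interferon-stimulated genes were called higher there more broadly than against vector (31 higher and 2 lower of 45, adjusted p = 2.69e-21, and adjusted p = 0.00414 with an estimated correlation). Estrogen receptor targets and cholesterol genes kept their direction (adjusted p = 8.87e-15 and 0.0325, and adjusted p = 0.311 and 0.531 with an estimated correlation), and protocadherins lost their call (adjusted p = 0.136).

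The 2K line was compared with the same vector. SHH, the secreted Sonic hedgehog signal (ENSG00000164690.8, chromosome 7, 155799986 to 155812273), rose from 6.36 ± 0.0984 to 44.4 ± 4.26 CPM (SD, n = 2 each), a log2 fold change of 2.80 (SE 0.142, adjusted p = 3.93e-08). BMP5, a bone morphogenetic protein (ENSG00000112175.8, chromosome 6, 55753645 to 55875564), rose from 7.72 ± 0.476 to 52.4 ± 0.283 CPM (log2 fold change 2.76, SE 0.0809, adjusted p = 6.62e-15). KRT17, a basal keratin (ENSG00000128422.17, chromosome 17, 41619441 to 41624842), fell from 9.87 ± 4.65 to 0.441 ± 0.0527 CPM (log2 fold change -4.47, SE 0.454, adjusted p = 8.33e-05). IL20, a cytokine of the interleukin-10 family (ENSG00000162891.10, chromosome 1, 206865354 to 206869223), fell from 8.42 ± 0.381 to 0.173 ± 0.113 CPM (log2 fold change -5.54, SE 0.248, adjusted p = 4.37e-12). The other genes named as higher were the matrix protein gene DMP1 (3.87), RAMP3, a partner of G protein-coupled receptors (3.35), PHLDA1 (2.76) and the zinc finger genes ZNF888 (3.20), ZNF257 (3.05), ZNF69 (2.90), ZNF90 (2.87) and ZNF486 (2.76). Those named as lower were SERPINE1, the plasminogen activator inhibitor (-5.68), STUM (-5.39), MMP13 (-5.28), LOXL4, a lysyl oxidase (-4.64), the growth factor BTC (-4.17), the keratin KRT6A (-4.02) and ANXA8 (-3.99). SPRR1B, a cornified envelope protein, had 1 count in the 2K libraries and 156 in the vector libraries, a 154-fold difference (95% counting interval 27.2 to 6100). KRT6A, ANXA8 and the zinc finger genes have near-identical relatives, so their exact values are uncertain.

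In 2K, 8021 genes were called, 4229 higher and 3792 lower, with 481 and 1031 changed at least 2-fold, and 3748 were called against a 1.2-fold change. The genes named all kept their calls without any library, but several sizes moved. Without vector replicate 1, SERPINE1 was at -5.08 and KRT17 at -3.88. Without 2K replicate 1, SERPINE1 was at -5.04 and MMP13 at -4.55, IL20 was 90.5-fold lower over 3 counts (95% counting interval 30.8 to 440), and SPRR1B was 73-fold lower over 1 count (12.9 to 2900). Without 2K replicate 2, SERPINE1 was at -6.75, STUM was 68-fold lower over 3 counts (23.1 to 331), and MMP13 was 105-fold lower over 2 counts (29 to 873). SPRR1B was then at 0 counts, at least 26.9-fold lower at a floor of 3 counts. Against the shScr line SHH (-0.32), RAMP3 (-0.14), ANXA8 (0.49) and MMP13, which had 1 count in shScr, were on the other side of 0. The calls of SERPINE1 (-0.91), KRT17 (-0.77), BTC (-0.54), KRT6A (-0.31) and SPRR1B were lost there, and BMP5 (0.61), IL20 (-1.39), STUM (-1.58) and LOXL4 (-0.96) kept theirs at smaller sizes.

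**Figure D2:**
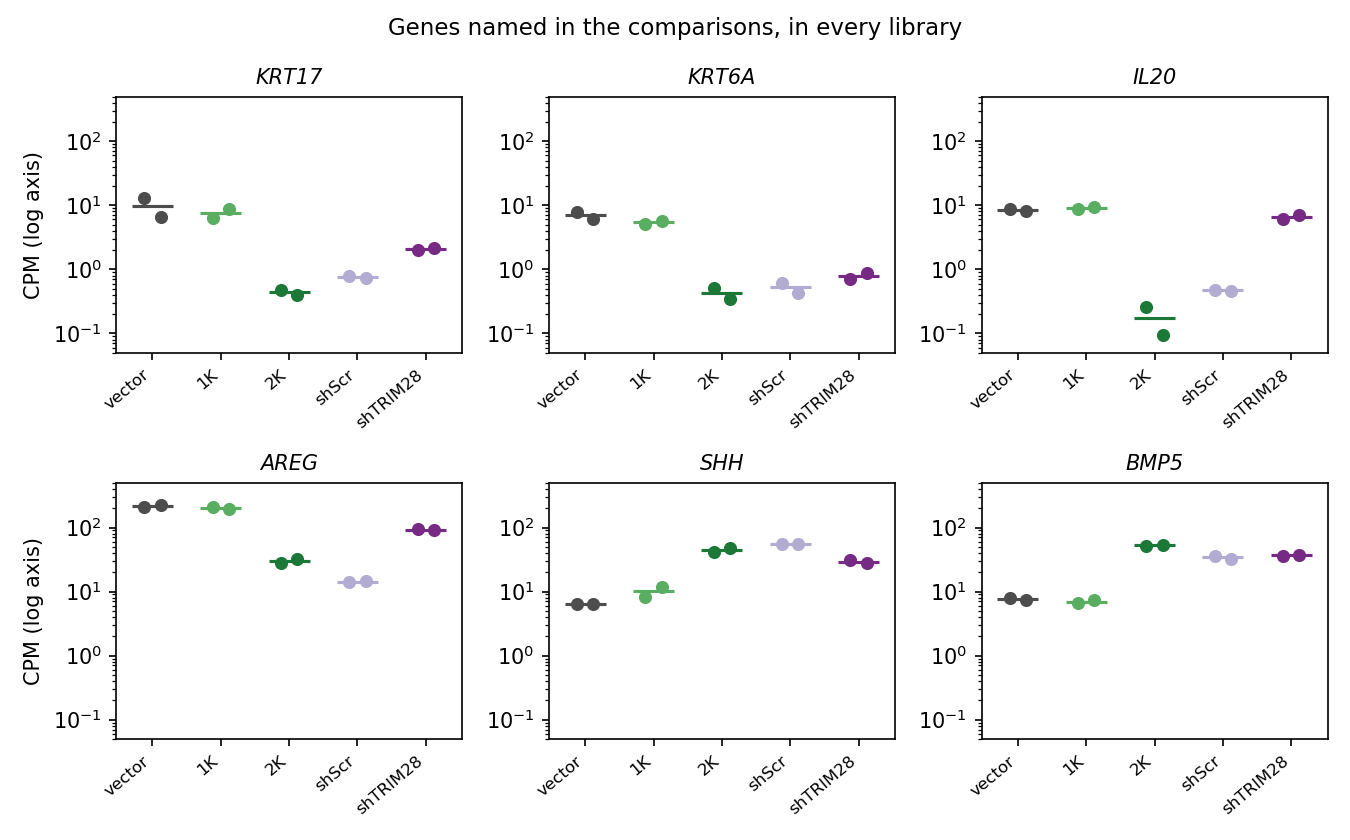
TMM-scaled CPM of KRT17, KRT6A, IL20, AREG, SHH and BMP5 in each of the 10 libraries on log axes, with points for libraries and a bar at the mean of each group. IL20 averaged 8.42 CPM in vector, 0.173 in 2K, 0.469 in shScr and 6.51 in shTRIM28, and BMP5 averaged 7.72 CPM in vector, 52.4 in 2K, 34.3 in shScr and 37 in shTRIM28.

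Proliferation genes rose in 2K: 43 of 48 measured members were higher and 5 did not pass, also adjusted over the list alone, with TK1 (log2 fold change 0.94), E2F2 (0.91), CCNE2 (0.90) and CDC25A (0.89) as examples (adjusted p = 1.02e-29, and adjusted p = 0.0285 with an estimated correlation). Replication-dependent histone genes rose in 40 of 42 cases, also adjusted over the list alone, with H2BC3 (1.30) and H3C2 (0.96) as examples (adjusted p = 6.39e-27, and adjusted p = 0.0261 with an estimated correlation), and near-identical copies make single histone genes uncertain. Cholesterol synthesis genes rose in 22 of 24 cases, also adjusted over the list alone, with STARD4 (1.37), ACAT2 (1.31), MVK (1.11) and LDLR, the low-density lipoprotein receptor (1.10) as examples (adjusted p = 1.06e-26, and adjusted p = 0.0261 with an estimated correlation). Of 30 p53 targets 23 fell and 1 rose, also adjusted over the list alone, with EDA2R (-1.61), FAS (-1.31), GADD45A (-1.27) and BTG2 (-1.23) as examples (adjusted p = 1.97e-11, and adjusted p = 0.0261 with an estimated correlation). Of 45 interferon-stimulated genes 27 fell and 1 rose (29 and 1 adjusted over the list alone), among them IFI44L (-2.47), RSAD2 (-2.11), DDX60 (-2.00) and IFI44 (-1.74), and the list was called lower (adjusted p = 6.87e-08, and adjusted p = 0.0261 with an estimated correlation). Of 272 KRAB zinc finger genes 168 rose and 19 fell (172 and 21 adjusted over the list alone), and the list was called higher (adjusted p = 1.25e-20, and adjusted p = 0.0261 with an estimated correlation). ZNF415 had 0 counts in vector and 30 in 2K, at least 10.2-fold higher at a floor of 3 counts over the group. ZNF135 was 16.3-fold higher (95% counting interval 5.24 to 81.6) and ZNF626 15.6-fold higher (5.01 to 78.3), each over 3 counts in vector. Without 2K replicate 1, 12 KRAB genes were lower in place of 19.

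Basal and myoepithelial markers were called lower in 2K (adjusted p = 1.85e-06, and adjusted p = 0.0781 with an estimated correlation). Of 19 members 12 fell and 2 rose, also adjusted over the list alone. They included KRT17 (-4.47), KRT6A (-4.02), TP63, the regulator of basal epithelium (-3.95), and KRT6B, 17.7-fold lower over 1 count in 2K (95% counting interval 2.8 to 738). Epithelial junction genes were called lower (adjusted p = 0.000862, and adjusted p = 0.172 with an estimated correlation). Of 30 members 12 fell and 3 rose (12 and 4 adjusted over the list alone), among them CLDN1 (-3.59), DSC2 (-2.93), DSG2 (-0.89) and DSP (-0.89). Estrogen receptor targets were called lower (adjusted p = 0.00161, and adjusted p = 0.538 with an estimated correlation). Of 38 members 17 fell and 7 rose (17 and 11 adjusted over the list alone), among them AREG, an epidermal growth factor family ligand (-2.86), PDZK1 (-2.42), HSPB8 (-2.26) and SERPINA1 (-1.03). Unfolded protein and stress response genes were called lower (adjusted p = 0.0029, and adjusted p = 0.172 with an estimated correlation). Of 30 members 11 fell and 9 rose (12 and 9 adjusted over the list alone). Those that fell most were PSAT1 (-3.81) and PHGDH (-2.04), both enzymes of serine synthesis, and DDIT4 (-2.03). Imprinted genes were called lower (adjusted p = 0.0108, and adjusted p = 0.0781 with an estimated correlation). Of 23 members 7 fell, among them the noncoding H19 (-3.63), and 4 rose, among them PHLDA2 (1.02), the same adjusted over the list alone, and 4 fell without vector replicate 2 and 2 rose without 2K replicate 2. Autophagy and lysosome genes were called lower (adjusted p = 0.0303, and adjusted p = 0.253 with an estimated correlation). Of 35 members 14 fell and 2 rose, also adjusted over the list alone, among them PRKAA2 (-2.88), GABARAPL1 (-0.89) and ULK1 (-0.81).

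The other 11 lists were not called in 2K. Of 23 TRIM28 corepressor genes 10 rose and 5 fell (11 and 5 adjusted over the list alone), among them UHRF1 (1.01), DNMT3B (0.53) and CHD3 (-0.40). Of 25 PRC2 and SWI/SNF subunits 7 rose and 6 fell (8 and 6 adjusted over the list alone), among them PHF19 (0.76) and AEBP2 (-0.46). Of 48 protocadherins 13 fell and 1 rose (12 and 1 adjusted over the list alone), and 7 fell without vector replicate 1 or without 2K replicate 1. Of 17 luminal markers 9 rose and 5 fell (10 and 5 adjusted over the list alone), among them AGR3 (2.05), AGR2 (1.71) and AR, the androgen receptor (-1.03). Of 22 mesenchymal genes 7 fell and 3 rose (9 and 3 adjusted over the list alone), with SNAI2 (-2.30) lower and VIM (1.84) and TWIST1 (1.58) higher. Hypoxia and glycolysis genes numbered 12 higher and 9 lower of 29, fibroblast and stromal markers 2 and 4 of 9, and neuronal genes 4 higher of 10, each the same adjusted over the list alone. Immediate early genes numbered 3 higher and 4 lower of 20, the same adjusted over the list alone, with MYC at -1.0 and 2 lower without 2K replicate 1. Cancer-testis genes numbered 2 higher and 2 lower of 5 (2 and 3 adjusted over the list alone), and ESAM (0.97) was the 1 of 5 leukocyte and endothelial markers called. Mean and test differed in sign for hypoxia genes (median 0.193, mean -0.0456, test up) and leukocyte markers (median -0.189, mean -0.0865, test up). Against the shScr line, 9240 genes were called in 2K, 3986 of them in the same direction as against vector. Proliferation (46 higher, 1 lower), cholesterol (22 higher), histone (39 higher, 1 lower) and p53 target genes (2 higher, 18 lower) kept their direction and their call there, with adjusted p = 0.0289, 0.033, 0.0289 and 0.033 with an estimated correlation. KRAB genes (121 higher, 50 lower) kept their direction (adjusted p = 0.00364) and lost the call with an estimated correlation (adjusted p = 0.161). Interferon-stimulated genes turned (21 higher and 6 lower, adjusted p = 0.0223, and adjusted p = 0.142 with an estimated correlation), as did estrogen receptor targets (17 higher and 9 lower, adjusted p = 0.00364, and adjusted p = 0.656 with an estimated correlation), and basal markers were not called (4 higher and 6 lower, adjusted p = 0.693). Junction, imprinted and autophagy genes lost their calls there (adjusted p = 0.431, 0.782 and 0.0895). Unfolded protein and stress response genes kept theirs (10 higher and 14 lower, adjusted p = 5.84e-05, and adjusted p = 0.1 with an estimated correlation).

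**Figure D3:**
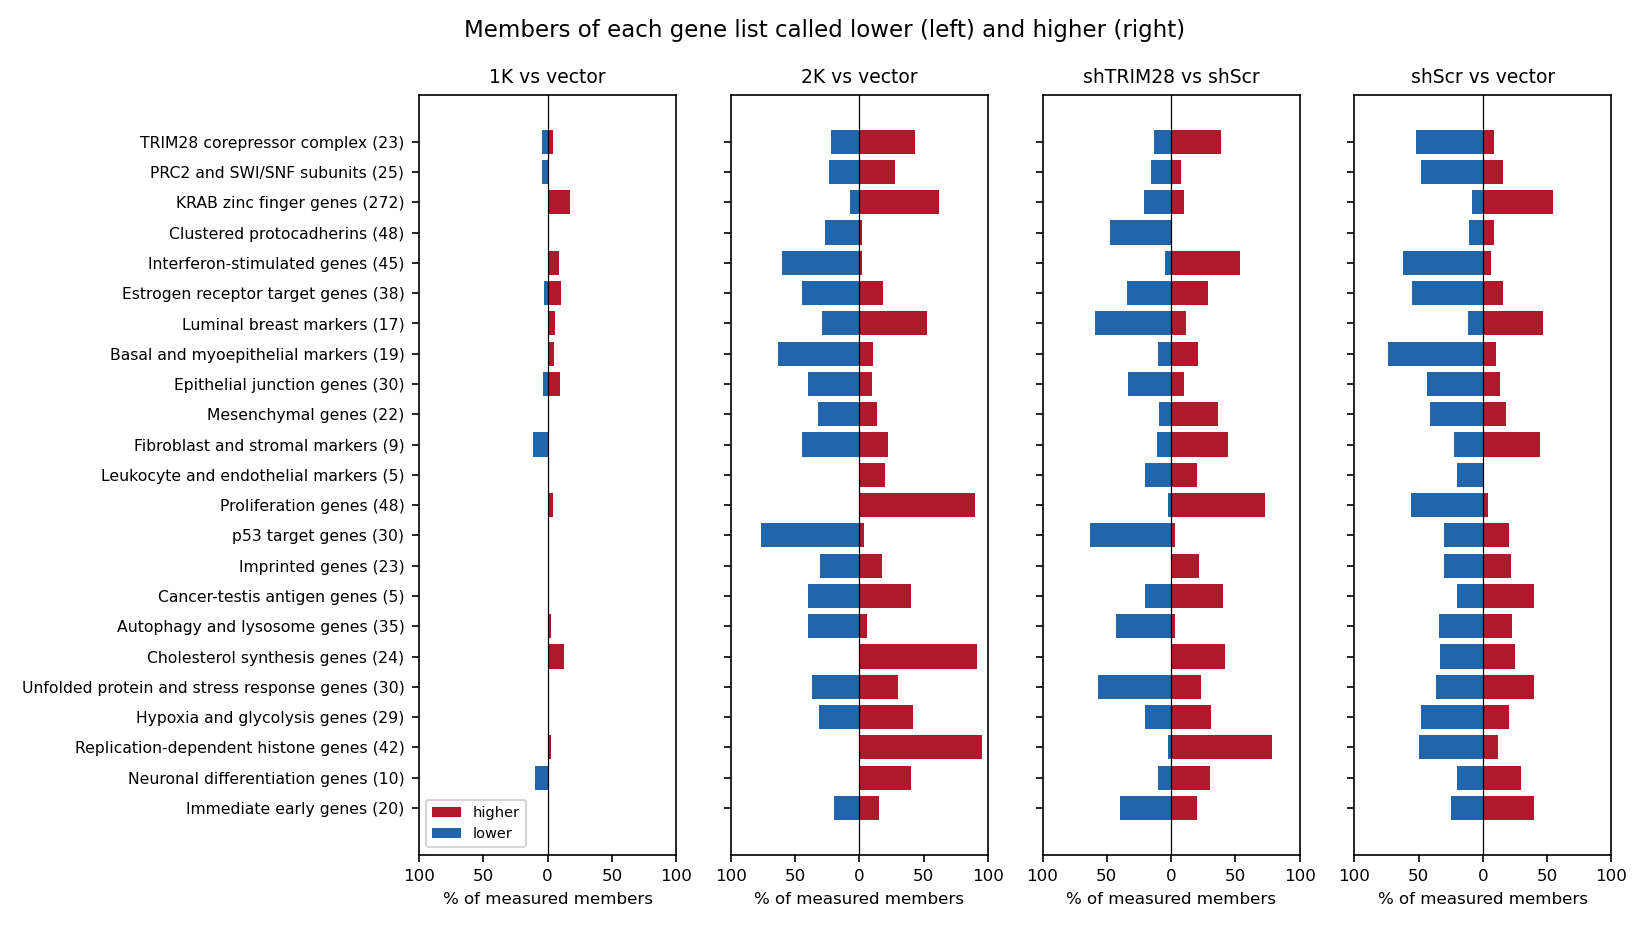
Percentage of the measured members of each of the 23 gene lists that were called higher (to the right) or lower (to the left) in 4 comparisons, with the number of measured members in parentheses. In 2K against vector 43 of 48 proliferation genes and 22 of 24 cholesterol genes were higher, and in the knockdown 24 of 45 interferon-stimulated genes were higher.

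The TRIM28 knockdown was compared with the scrambled shRNA to ask what loss of the corepressor changes. AREG (ENSG00000109321.11, chromosome 4, 74445134 to 74455009) rose from 14.1 ± 0.348 to 91.9 ± 2.61 CPM (SD, n = 2 each), a log2 fold change of 2.70 (SE 0.0707, adjusted p = 2.48e-15). IL20 rose from 0.469 ± 0.0125 to 6.51 ± 0.711 CPM (log2 fold change 3.79, SE 0.203, adjusted p = 1.55e-10). MGP, matrix Gla protein (ENSG00000111341.10, chromosome 12, 14881181 to 14885926), rose from 9.04 ± 0.585 to 75.7 ± 0.276 CPM (log2 fold change 3.06, SE 0.164, adjusted p = 8.63e-06). S100P, a calcium-binding protein (ENSG00000163993.7, chromosome 4, 6693069 to 6697170), fell from 50.7 ± 0.111 to 11.1 ± 0.453 CPM (log2 fold change -2.18, SE 0.131, adjusted p = 4.06e-07). The other genes named as higher were CALB2, which encodes calretinin (3.76), the adaptor AFAP1L2 (3.18), the flippase ATP8A2 (3.15), the deiodinase DIO2 (3.12), PSAT1 (2.89), RGL3 (2.77) and TP63 (2.71). Those named as lower were PTPRN2 (-3.21), the mitochondrial enzyme DMGDH (-2.41), the urea transporter SLC14A1 (-2.00), TGFBI, an extracellular matrix protein (-1.96), NIBAN1 (-1.95), the protease CAPN9 (-1.92), ACTG2, a smooth muscle actin (-1.92), the transcription factor KLF2 (-1.91) and SIGLEC15 (-1.89).

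In the knockdown, 5729 genes were called, 3114 higher and 2615 lower, with 545 and 256 changed at least 2-fold. Against a 1.2-fold change 1889 were called, and without shScr replicate 1 there were 3715. The 20 genes named kept their calls without any library. Against vector in place of shScr, IL20 (-0.37), AFAP1L2 (-0.84), ATP8A2 (-1.41), MGP (-0.32), TP63 (-2.10) and AREG (-1.24), named as higher, and NIBAN1 (0.0096), ACTG2 (0.11) and KLF2 (0.39), named as lower, were on the other side of 0. The calls of PSAT1 (0.13) and PTPRN2 (-0.88) were lost there.

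Interferon-stimulated genes rose in the knockdown: 24 of 45 were higher and 2 lower (30 and 2 adjusted over the list alone), among them DDX60 (log2 fold change 2.00), XAF1 (1.94), OAS2 (1.90) and IFI27 (1.76), and the list was called higher (adjusted p = 2.97e-09, and adjusted p = 0.0382 with an estimated correlation). Proliferation genes were called higher (adjusted p = 1.4e-14, and adjusted p = 0.112 with an estimated correlation). Of 48 members 35 rose and 1 fell (38 and 2 adjusted over the list alone), among them MYBL2 (0.82), CDC6 (0.76) and TK1 (0.71). Histone genes were called higher (adjusted p = 4.26e-13, and adjusted p = 0.112 with an estimated correlation). Of 42 members 33 rose and 1, H4C9 (-0.65), fell (34 and 1 adjusted over the list alone). Cholesterol synthesis genes were called higher (adjusted p = 0.000684, and adjusted p = 0.288 with an estimated correlation). Of 24 members 10 rose (11 adjusted over the list alone), among them ACAT2 (1.03) and SQLE (0.63). Of 30 p53 targets 19 fell and 1 rose (21 and 1 adjusted over the list alone), with BTG2 (-0.93) and PMAIP1 (-0.78) lower and TP53I3 (0.92) higher, and the list was called lower (adjusted p = 6.13e-07, and adjusted p = 0.0869 with an estimated correlation). Luminal markers were called lower (adjusted p = 7.72e-08, and adjusted p = 0.189 with an estimated correlation). Of 17 members 10 fell and 2 rose (13 and 2 adjusted over the list alone), among them AGR3 (-1.59), MLPH (-1.07), SPDEF (-1.06) and MUC1 (-0.84). Unfolded protein and stress response genes were called lower (adjusted p = 1.64e-05, and adjusted p = 0.112 with an estimated correlation). Of 30 members 17 fell and 7 rose (18 and 7 adjusted over the list alone), among them DDIT3 (-1.09) and TRIB3 (-0.90), with PSAT1 higher (2.89). Autophagy and lysosome genes were called lower (adjusted p = 6.06e-05, and adjusted p = 0.112 with an estimated correlation). Of 35 members 15 fell and 1 rose, also adjusted over the list alone, among them CTSL (-0.63) and SQSTM1 (-0.47). The 1 that rose was PRKAA2, 33.4-fold over 1 count in shScr (95% counting interval 5.61 to 1360).

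Clustered protocadherins were called lower in the knockdown (adjusted p = 6.29e-07, and adjusted p = 0.201 with an estimated correlation). Of 48 members 23 fell and 25 did not pass (25 falling adjusted over the list alone), among them PCDHGA8 (-1.0), PCDHGA7 (-0.99) and PCDHB15 (-0.76). Without shScr replicate 2, 11 fell, and without shTRIM28 replicate 1, 14 fell, and the shared exons of these clusters make single members uncertain. Of 272 KRAB zinc finger genes 58 fell and 28 rose (60 and 31 adjusted over the list alone), among them ZNF491 (-1.34) and ZNF528 (-1.0), with ZNF569 higher (0.80), and the list was called lower (adjusted p = 0.0471, and adjusted p = 0.288 with an estimated correlation). Without shScr replicate 1, 31 KRAB genes fell and 11 rose, without shScr replicate 2, 38 and 15, without shTRIM28 replicate 1, 35 and 15, and without shTRIM28 replicate 2, 32 and 9. Mesenchymal genes were called higher (adjusted p = 0.00169, and adjusted p = 0.189 with an estimated correlation). Of 22 members 8 rose and 2 fell (10 and 2 adjusted over the list alone), among them TGFB1 (1.45), with TGFBI (-1.96) and CD44 (-1.47) lower. Without shScr replicate 1, shScr replicate 2 or shTRIM28 replicate 1, 4 of them rose. Fibroblast and stromal markers were called higher (adjusted p = 0.00856, and adjusted p = 0.201 with an estimated correlation). Of 9 members 4 rose and 1 fell (5 and 1 adjusted over the list alone), among them MGP (3.06) and COL6A1 (0.97), with COL6A3 (-1.38) lower, and 2 rose without shScr replicate 1, shScr replicate 2 or shTRIM28 replicate 1.

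The other 11 lists were not called in the knockdown. Of 38 estrogen receptor targets 11 rose and 13 fell (12 and 13 adjusted over the list alone), with AREG (2.70), PDZK1 (1.87) and HSPB8 (1.83) higher and ELOVL2 (-1.45) lower. Without shScr replicate 1, 6 fell, without shScr replicate 2, 8, and without shTRIM28 replicate 2, 7. Of 19 basal and myoepithelial markers 4 rose and 2 fell (5 and 2 adjusted over the list alone), with TP63 (2.71) and KRT16 (0.91) higher and LAMA3 (-0.76) lower. Without shScr replicate 1 or shTRIM28 replicate 1, 2 of them rose, and without shScr replicate 2 or shTRIM28 replicate 2, 1. Of 30 epithelial junction genes 10 fell and 3 rose (13 and 5 adjusted over the list alone), with CLDN1 (2.58) and DSC2 (1.84) higher and CDH1, which encodes E-cadherin (-0.50), lower. Of 23 TRIM28 corepressor genes 9 rose and 3 fell (11 and 4 adjusted over the list alone), among them UHRF1 (0.48) and CBX5 (0.45). Of 23 imprinted genes 5 rose, also adjusted over the list alone, among them H19 (1.79). PRC2 and SWI/SNF subunits numbered 2 higher and 4 lower of 25, neuronal genes 3 and 1 of 10, cancer-testis genes 2 and 1 of 5, and leukocyte and endothelial markers 1 and 1 of 5, each the same adjusted over the list alone. Of the PRC2 and SWI/SNF subunits 2 were lower without shScr replicate 1 or shTRIM28 replicate 2 and 1 without shScr replicate 2 or shTRIM28 replicate 1, and 1 neuronal gene was higher without shScr replicate 1 or shScr replicate 2. Hypoxia and glycolysis genes numbered 9 higher and 6 lower of 29 (9 and 7 adjusted over the list alone), with 5 higher without shScr replicate 2. Immediate early genes numbered 4 higher and 8 lower of 20 (5 and 8 adjusted over the list alone), with 5 lower without shTRIM28 replicate 2. Median, mean and test differed in sign for estrogen receptor targets (-0.0349, 0.0998, up), junction genes (-0.107, 0.0397, down), cancer-testis genes (-0.0659, 0.0995, down) and leukocyte markers (0.11, -0.327, down). Against vector in place of shScr, 8144 genes were called, 1963 of them in the same direction as against shScr. Interferon-stimulated genes turned there (5 higher and 21 lower, adjusted p = 0.000118), as did KRAB genes (114 higher and 14 lower, adjusted p = 5.68e-06), while p53 targets (1 higher and 18 lower, adjusted p = 4.71e-06) and protocadherins (24 lower, adjusted p = 0.00019) kept their direction. With an estimated correlation all 4 calls were lost, at adjusted p = 0.114 for the first 3 and adjusted p = 0.374 for protocadherins. Mesenchymal genes pointed down and were not called against vector (adjusted p = 0.196), and proliferation, luminal, stress response and fibroblast lists lost their calls (adjusted p = 0.105, 0.737, 0.0818 and 0.134). Histone, cholesterol and autophagy genes kept direction and call (adjusted p = 0.00282, 0.0323 and 0.000287), and the call was lost with an estimated correlation (adjusted p = 0.374, 0.458 and 0.14).

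The 2 fragments were compared directly, with 2K against 1K. BMP5 rose from 6.95 ± 0.496 CPM in 1K to 52.4 ± 0.283 in 2K (SD, n = 2 each), a log2 fold change of 2.91 (SE 0.0823, adjusted p = 5.06e-15). PCDH7, a protocadherin outside the clusters (ENSG00000169851.15, chromosome 4, 30720415 to 31146805), rose from 29.3 ± 5.11 to 187 ± 11 CPM (log2 fold change 2.67, SE 0.0966, adjusted p = 1.89e-09). The other genes named were BRINP3 (2.67), DMP1 (2.61) and KLHL4 (2.50) as higher and IL20 (-5.66), SERPINE1 (-4.66), STUM (-4.62), LOXL4 (-4.31) and MMP13 (-4.28) as lower. In all 6824 genes were called, 3510 higher and 3314 lower, with 314 and 796 changed at least 2-fold, and 2941 against a 1.2-fold change. SERPINE1 lost its call without 2K replicate 1 (-4.01) and without 2K replicate 2 (-5.71), and with only these 2 groups in the fit, and was at -3.77 without 1K replicate 2. Without 2K replicate 1, MMP13 was at -3.55 and IL20 was 98.3-fold lower over 3 counts (95% counting interval 33.5 to 478). Without 2K replicate 2, STUM was 39.7-fold lower over 3 counts (13.4 to 194) and MMP13 52.2-fold lower over 2 counts (14.3 to 434).

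Between 2K and 1K, the lists called higher and kept with an estimated correlation were proliferation genes (44 of 48 higher and 1 lower, adjusted p = 1.57e-30), histone genes (39 of 42 higher, adjusted p = 1.53e-29), cholesterol genes (21 of 24 higher, adjusted p = 8.86e-22) and KRAB genes (141 of 272 higher and 17 lower, adjusted p = 1.6e-09), each with adjusted p = 0.0318 with an estimated correlation. Adjusted over the list alone, the counts were 45 and 1, 39 higher, 22 and 1, and 146 and 21. Those called lower and kept were p53 targets (23 of 30 lower and 1 higher, adjusted p = 1.1e-14, and adjusted p = 0.0149 with an estimated correlation) and interferon-stimulated genes (32 of 45 lower and 2 higher, adjusted p = 7.08e-15, and adjusted p = 0.0114 with an estimated correlation). Adjusted over the list alone, the counts were 23 and 1, and 34 and 2. Estrogen receptor targets (20 of 38 lower and 5 higher, 21 and 5 adjusted over the list alone), with PDZK1 at -3.17 and AREG at -2.74, were called lower (adjusted p = 3.63e-07, and adjusted p = 0.299 with an estimated correlation), and 12 were lower without 1K replicate 1. Basal markers (12 of 19 lower and 2 higher, 12 and 3 adjusted over the list alone) were called lower (adjusted p = 2.23e-05, and adjusted p = 0.0896 with an estimated correlation). Junction genes (12 of 30 lower and 1 higher, 13 and 2 adjusted over the list alone) were called lower (adjusted p = 7.13e-05, and adjusted p = 0.107 with an estimated correlation). Unfolded protein and stress response genes (12 of 30 lower and 7 higher, 14 and 8 adjusted over the list alone) were called lower (adjusted p = 2.39e-05, and adjusted p = 0.0768 with an estimated correlation). Imprinted genes (7 of 23 lower and 4 higher) and autophagy genes (15 of 35 lower and 1 higher), with the same counts adjusted over the list alone, were called lower at adjusted p = 0.0197 and adjusted p = 0.0269, and had adjusted p = 0.0896 and adjusted p = 0.198 with an estimated correlation. Without 1K replicate 1 or 2K replicate 1, 4 imprinted genes were lower, and without 1K replicate 2 or 2K replicate 2, 4 stress response genes were higher. The other 11 lists were not called.

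The control lines were compared with each other, shScr against vector, as a measure of how far lines with no targeting construct differ. CYP24A1, the vitamin D hydroxylase (ENSG00000019186.10, chromosome 20, 54153449 to 54173973), fell from 35.7 ± 5.24 CPM in vector to 0.999 ± 0.231 in shScr (SD, n = 2 each), a log2 fold change of -5.17 (SE 0.386, adjusted p = 6.99e-05). RAMP3 (ENSG00000122679.8, chromosome 7, 45157791 to 45186302) rose from 10.8 ± 1.68 to 121 ± 1.97 CPM (log2 fold change 3.48, SE 0.17, adjusted p = 2.67e-06). The other genes named were BRINP2 (4.58), SIM1 (3.42), PPFIA2 (3.17) and SHH (3.12) as higher and ANXA8L1 (-4.86) and TP63 (-4.81) as lower. MMP13 had 1 count in shScr and 408 in vector, 468-fold lower (95% counting interval 83.5 to 18500), and SPRR1B had 3 and 156, 59.6-fold lower (20 to 292). The comparison called 9416 genes, 4634 higher and 4782 lower, with 1189 and 1183 changed at least 2-fold, and 5056 against a 1.2-fold change, more than any of the 3 main comparisons. Without vector replicate 1, BRINP2 was at 3.96, and without vector replicate 2, BRINP2 was at 5.54 and SIM1 at 4.04. Without shScr replicate 1, MMP13 was at 0 counts, at least 73.1-fold lower at a floor of 3 counts, and ANXA8L1 was 56.2-fold lower over 2 counts (95% counting interval 15.4 to 467). SPRR1B was then 41.9-fold lower over 2 counts (11.4 to 349). Without shScr replicate 2, MMP13 was 249-fold lower over 1 count (44.4 to 9840) and SPRR1B 95-fold lower over 1 count (16.8 to 3780). ANXA8L1 shares most of its sequence with ANXA8.

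In shScr against vector, interferon-stimulated genes were called lower (adjusted p = 3.6e-13, and adjusted p = 0.0226 with an estimated correlation). Of 45 members 28 fell and 3 rose (29 and 3 adjusted over the list alone), among them SAMD9 (-2.93) and DDX60 (-2.90). KRAB zinc finger genes were called higher (adjusted p = 1.49e-07, and adjusted p = 0.128 with an estimated correlation). Of 272 members 149 rose and 23 fell (154 and 27 adjusted over the list alone), among them ZNF90 (1.66) and ZNF442 (1.62). Basal markers were called lower (adjusted p = 1.71e-06, and adjusted p = 0.162 with an estimated correlation). Of 19 members 14 fell and 2 rose, also adjusted over the list alone, among them TP63 (-4.81) and KRT17 (-3.70), and KRT6B at 18 counts in vector and 0 in shScr, at least 6.88-fold lower. Estrogen receptor targets were called lower (adjusted p = 5.97e-09, and adjusted p = 0.414 with an estimated correlation). Of 38 members 21 fell and 6 rose, also adjusted over the list alone, among them AREG (-3.94) and HSPB8 (-2.64). Proliferation genes were called lower (adjusted p = 0.000241, and adjusted p = 0.445 with an estimated correlation). Of 48 members 27 fell and 2 rose (27 and 3 adjusted over the list alone), among them MKI67 (-1.07). Histone genes were called lower (adjusted p = 0.031, and adjusted p = 0.574 with an estimated correlation). Of 42 members 21 fell and 5 rose (22 and 5 adjusted over the list alone), and 12 fell without shScr replicate 2. Luminal markers were called higher (adjusted p = 0.00159, and adjusted p = 0.459 with an estimated correlation). Of 17 members 8 rose and 2 fell, also adjusted over the list alone, among them AGR3 (2.76) and TFF3 (2.01). Mesenchymal genes (9 of 22 lower and 4 higher) were called lower (adjusted p = 0.00228, and adjusted p = 0.273 with an estimated correlation), as were junction genes (13 of 30 lower and 4 higher, adjusted p = 0.0464, and adjusted p = 0.445 with an estimated correlation), with the same counts adjusted over the list alone. Hypoxia genes (14 of 29 lower and 6 higher, 15 and 6 adjusted over the list alone) were called lower (adjusted p = 0.0464, and adjusted p = 0.597 with an estimated correlation). Imprinted genes (7 of 23 lower and 5 higher, also adjusted over the list alone) were called lower (adjusted p = 0.0487, and adjusted p = 0.273 with an estimated correlation), with a median of 0.0453, a mean of -0.113 and H19 at -3.93. Some counts of risen members dropped without a library. For estrogen receptor targets 3 rose without vector replicate 1 and 2 without shScr replicate 1, and for histone genes 2 without vector replicate 1, 3 without vector replicate 2 and 2 without shScr replicate 1. For mesenchymal genes 2 rose without vector replicate 1, for junction genes 2 without shScr replicate 1, and for imprinted genes 2 without vector replicate 2, 3 without shScr replicate 1 and 2 without shScr replicate 2. The other 12 lists were not called.

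The effects of the fragments and of the knockdown were compared gene by gene. Between 1K and 2K, 200 genes were higher in both, where 65.7 would be shared by chance, and 137 lower in both, where 36.2 would be, while 45 moved in opposite directions against 99.2 by chance. These comparisons share the vector libraries. In 20 simulated draws of unchanged groups against them at most 1 gene was shared in each direction, but only 2.75 and 2.5 were called on average, too few to gauge it. With as many genes taken by p in each draw as were called in the data, a test added after the data were seen, a mean of 217 were shared higher (211 to 227) and 128 lower (121 to 141). The overlap thus does not separate a shared effect from the shared vector libraries. Between 1K and the knockdown, 80 genes were higher in both (48.4 by chance), 47 lower in both (24.9) and 139 opposite (70.3). Between 2K and the knockdown, 1142 were higher in both (686 by chance), 755 lower in both (517) and 1472 opposite (1192). Across the 19190 genes, which are not independent replicates, the log2 fold changes of 1K and 2K correlated at r = 0.452, against a mean of 0.496 in the simulated draws. The observed covariance of 0.121 exceeded the simulated 0.0466 by 0.0744. Those of 1K and the knockdown correlated at r = -0.0262, and those of 2K and the knockdown at r = -0.146 with Spearman's rho of 0.0439, so the sign for the latter pair depended on the measure.

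In the 3 main comparisons together, 216 genes were called in each, 79 in the same direction (44 higher and 35 lower) and 97 with both fragments one way and the knockdown the other (54 higher and 43 lower with the fragments). DMP1 rose by 1.26, 3.87 and 1.97 on the log2 scale in 1K, 2K and the knockdown, and TAS1R3 by 1.77, 0.91 and 1.06. ZNF569 rose by 0.83, 1.86 and 0.80, PMP22, a myelin protein, by 0.65, 1.07 and 0.97, and the estrogen-responsive receptor GPER1 by 0.77, 0.96 and 0.63. KLK6 changed by -0.91, -2.69 and -1.35, PSG5 by -1.15, -2.45 and -0.81, SERHL2 by -1.04, -1.01 and -1.05, SULF1, a heparan sulfatase, by -0.72, -0.82 and -1.07, and PLCXD3 by -0.61, -1.36 and -0.74. In opposite directions, SIM1 changed by 1.14, 1.46 and -1.24, RAMP3 by 1.06, 3.35 and -0.98, AGR3, a luminal secretory protein, by 0.94, 2.05 and -1.59, and COLEC10 by -1.09, -3.28 and 1.18. MMP13 changed by -1.0 in 1K and -5.28 in 2K, and rose 23.6-fold in the knockdown over 1 count in shScr (95% counting interval 3.85 to 970). These patterns depend on the control line. With vector and shScr exchanged, SIM1 (-2.28, -1.96 and 2.18), RAMP3 (-2.43, -0.14 and 2.51), AGR3 (-1.82, -0.71 and 1.17) and MMP13 changed sign in all 3 comparisons, and COLEC10 in 1K (1.48) and the knockdown (-1.39), with its call in 2K lost (-0.72). Among the genes that moved alike, PMP22 changed sign in 1K (-0.57) and 2K (-0.15), KLK6 in 1K (0.92), and TAS1R3 (-0.092) and SULF1 (0.67) in the knockdown, and PSG5 (-0.044) and PLCXD3 (-0.073) lost their 1K calls. Some calls were also lost without a library. For DMP1 in 1K the values were 0.98 without vector replicate 2 and 1.09 without 1K replicate 1, and for RAMP3 in 1K 0.90 without vector replicate 1, 1.22 without vector replicate 2, 0.91 without 1K replicate 1 and 1.2 without 1K replicate 2. For TAS1R3 they were 0.68 without vector replicate 2 and 0.70 without 2K replicate 1 in 2K, and 0.96 without shScr replicate 1 and 0.91 without shTRIM28 replicate 1 in the knockdown. For ZNF569 in 1K they were 0.87 without vector replicate 1, 0.79 without vector replicate 2, 0.82 without 1K replicate 1 and 0.84 without 1K replicate 2, and in the knockdown 0.61 without shTRIM28 replicate 2. For PSG5 in the knockdown they were -0.62 without shScr replicate 1, -0.88 without shTRIM28 replicate 1 and -0.74 without shTRIM28 replicate 2, and in 2K PSG5 was at -3.30 without 2K replicate 2. PLCXD3 in 1K was at -0.40 without 1K replicate 2, and SIM1 in 2K at 2.08 without vector replicate 2, each still called. MMP13 was at least 3.69-fold higher in the knockdown without shScr replicate 1, where shScr was at 0 counts, and 12.5-fold higher over 1 count (95% counting interval 2.04 to 515) without shScr replicate 2. The 1K calls of DMP1, ZNF569, PLCXD3, RAMP3 and PMP22 and the knockdown call of PSG5 were also lost against a 1.2-fold change, those of DMP1, ZNF569 and PLCXD3 with only these 2 groups in the fit, that of RAMP3 with the GC and length correction and that of ZNF569 with DESeq2.

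The differences between effects were tested as well. The shTRIM28 effect minus the 1K effect was called for 4053 genes, 2040 higher and 2013 lower, with 1535 called against a 1.2-fold change and 2611 without shScr replicate 1. The shTRIM28 effect minus the 2K effect was called for 6420 genes, 3158 higher and 3262 lower, with 3575 called against a 1.2-fold change. With the 2 control lines exchanged in both effects (chosen after the data were seen), 10400 and 9825 genes were called. Of the genes called both ways 695 of 2777 and 1433 of 3855 kept direction. The exchange itself adds the control difference, so it cannot test the differences.

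List tests on these differences were also added after the data were seen. Interferon-stimulated genes were higher in the knockdown effect than in the 2K effect, with 33 of 45 members called (33 adjusted over the list alone, adjusted p = 1.66e-15, and adjusted p = 0.0146 with an estimated correlation). With the controls exchanged they were lower (adjusted p = 0.000132). KRAB genes were lower there, with 153 of 272 lower and 13 higher (167 and 16 adjusted over the list alone, adjusted p = 7.03e-18, and adjusted p = 0.0155 with an estimated correlation), and not called with the controls exchanged (adjusted p = 0.49). Proliferation genes were lower than in 2K (29 lower and 2 higher, also adjusted over the list alone, adjusted p = 8.28e-05, and adjusted p = 0.409 with an estimated correlation), also with the controls exchanged (adjusted p = 6.7e-19). The other 8 of 11 lists called lost the call with an estimated correlation. They were estrogen receptor targets, basal, mesenchymal, p53 target and imprinted genes as higher (adjusted p = 0.000143, 2.82e-05, 0.00395, 0.0284 and 0.00132), and luminal, cholesterol and histone genes as lower (adjusted p = 1.15e-06, 8.44e-10 and 0.000129). With the controls exchanged only cholesterol (adjusted p = 2.25e-08) and histone genes (adjusted p = 4.11e-11) of these 8 kept direction and call, and estrogen receptor targets, basal and mesenchymal genes were called lower.

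Against the 1K effect 13 lists were called, and none kept the call with an estimated correlation. Of the KRAB genes 83 were lower and 4 higher (97 and 6 over the list alone, adjusted p = 3.48e-09, and adjusted p = 0.0882 with an estimated correlation), and 17 interferon-stimulated genes were higher and 3 lower (22 and 3 adjusted over the list alone, adjusted p = 0.000147, and adjusted p = 0.0882 with an estimated correlation). Of the interferon-stimulated genes 11 were higher without vector replicate 1 or shTRIM28 replicate 2 and 9 without shScr replicate 1, and 1 was lower without shTRIM28 replicate 1. Of the KRAB genes 8 were higher without vector replicate 2 and 2 without shTRIM28 replicate 2. Proliferation genes were higher than in 1K (29 higher and 3 lower, 32 and 3 adjusted over the list alone, adjusted p = 1.28e-08, and adjusted p = 0.178 with an estimated correlation). The other 10 were histone, mesenchymal, fibroblast and imprinted genes as higher (adjusted p = 1.28e-08, 0.00928, 0.00536 and 0.0367), and luminal, p53 target, stress response, autophagy, protocadherin and immediate early genes as lower (adjusted p = 4.01e-09, 3.8e-06, 8.09e-06, 0.00137, 0.00878 and 0.0487). With the controls exchanged only p53 targets kept direction and call (adjusted p = 0.0076). KRAB, interferon-stimulated and mesenchymal genes were called the other way (adjusted p = 0.000596, 4.33e-14 and 0.0115), and proliferation genes pointed down and were not called (adjusted p = 0.0845).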

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

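All tests of explanations here except that of chromosome segments were chosen after the result was seen, as were the comparisons with the other control line, the exchange of both control lines and the GC and length correction.

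The shTRIM28 effect (against shScr) and the 1K effect (against vector) differed in an interaction test for 4053 genes. The difference of log2 fold changes was -0.63 for TRIM28 and -0.96 for ZNF568. The other genes named by the rule were MMP13 (5.23), DIO2 (4.12), IL20 (3.67), ATP8A2 (3.53), the connexin GJA1 (3.52), PTPRN2 (-3.50), C9orf152 (-2.93), BRINP2 (-2.84), MPPED2 (-2.76) and TGFBI (-2.61). MMP13 had 1 count in the shScr libraries, so its fitted difference depends on the prior count. Without shScr replicate 1 the number of genes called was 2611. MMP13 then had 0 counts in shScr and GJA1 had 2, and without shScr replicate 2 MMP13 had 1, so no difference is given for these, while GJA1 was at 2.91 without shScr replicate 2. Without vector replicate 1 DIO2 was at 3.42 and BRINP2 at -2.22, and without vector replicate 2 BRINP2 was at -3.79. With the 2 control lines exchanged, only TRIM28 (-0.43) and TGFBI (-3.42) kept sign and call. ZNF568 (0.60) and the other 9 genes were on the other side of 0, a shift the exchange itself adds.

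The shTRIM28 effect and the 2K effect differed for 6420 genes, by -0.73 for TRIM28 and -1.11 for ZNF568. The genes named were MMP13 (9.52), IL20 (9.33), SERPINE1 (6.89), PSAT1 (6.70), TP63 (6.66), RAMP3 (-4.33), SHH (-3.73), AGR3 (-3.64), ZNF257 (-3.34) and ZNF90 (-3.26), and the MMP13 value again rests on 1 count in shScr. The call of SERPINE1 was lost without 2K replicate 1 (6.24), shScr replicate 1 (7.16), shScr replicate 2 (6.68), shTRIM28 replicate 1 (6.67) or shTRIM28 replicate 2 (7.11). SERPINE1 was at 6.28 without vector replicate 1 and at 7.95 without 2K replicate 2. No difference is given for MMP13 without a library, since it had at most 1 count in shScr, nor for IL20 without 2K replicate 1, where 3 counts were left in 2K. TP63 was at 6.03 without 2K replicate 1 and 7.69 without 2K replicate 2. With the control lines exchanged, TRIM28 (-0.53), PSAT1 (1.17) and ZNF257 (-1.28) kept sign and call, and IL20 (1.02) lost its call. ZNF568 (0.45), SERPINE1, TP63, RAMP3, SHH, AGR3, ZNF90 and MMP13 were on the other side of 0.

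KRAB zinc finger genes were higher in 1K and in 2K than in vector. Whether reads of an expressed fragment were counted on KRAB genes cannot be told apart from a rise of these genes: ZNF568 ranked 68 in 1K and 129 in 2K of the 272 measured, but the labels do not give the sequence or species of the fragments. A GC or length trend as the whole cause is argued against by 170 members still called higher in 2K and 57 in 1K after correction. For 2K, low levels in the vector libraries as the whole cause are argued against by 2K against 1K, which uses no vector library: the median was 0.284, with 141 members higher and 17 lower (adjusted p = 0.0318 with an estimated correlation). For 1K the median against shScr was -0.0617, as low levels in the vector libraries would give, so that explanation stays open there. An effect of the fragments on these genes stays open as a hypothesis, as do differences between lines of other origin.

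Basal and myoepithelial markers were lower in 2K than in vector. High levels in the vector libraries alone are argued against by 2K against 1K, with no vector library. The median was -0.794, with 12 of 19 lower and 2 higher. That list call was lost with an estimated correlation (adjusted p = 0.0896) and kept by fry (adjusted p = 0.000847). Against shScr the 2K median was 0.144 (0.0386 without KRT6B, at the floor in both) and the 1K median 0.926. As shScr was as low, high levels shared by vector and 1K stay open. Basal cells of another origin among the vector cells are argued against, since KRT5 and KRT14 summed to 0.31 CPM in vector beside 13.2 and 6.58 CPM of KRT17. A GC or length trend as the whole cause is argued against by 12 members still called lower after correction. An effect of 2K on these markers stays open as a hypothesis, as do differences between lines of other origin.

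More genes were called between shScr and vector than in the 1K, 2K or knockdown comparison. A single aberrant vector library is argued against, since at least 7931 genes were called without either one, and a GC or length trend is argued against by 9501 genes called after correction. Copy number differences over large chromosome segments as the whole cause are argued against: blocks of 50 consecutive genes held 5.31% of the variance of the log2 fold changes beyond permuted gene order. The vector type, selection and drift between stable lines stay open, since no library of the design separates them.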

How the results depend on the processing

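The other control line, the exchange of both control lines and the GC and length correction were chosen after the data were seen, and the other alternatives were planned.

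Of 141 results for named genes, 66 kept direction and call under every alternative run. Of 1893 alternatives of these results, 1743 did, 97 only lost the call, and 53 reversed sign, called or not. RLE size factors kept all 141, DESeq2 and the GC correction 138 each, the replicate block, no low-count filter and the stricter filter 140 each, only the groups of the comparison 131 and glmTreat 125. Leave-outs kept 596 and ended the call in 48, where the group left with 1 library was assumed to vary like the others. Of the counts and their alternatives, 83 stayed within 1.5 times and 14 did not. TRIM28 in the knockdown stayed called in every alternative run, between -0.39 and -0.47, or at -0.33 against vector.

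In 1K, 1117 genes were called with no low-count filter and 8639 against shScr. With only the groups of the comparison 138 were, and knockdown calls rose to 7428. Against a 1.2-fold change, a stricter null by construction, the counts were 73 in 1K, 3748 in 2K, 1889 in the knockdown, 2941 for 2K against 1K, 5056 for shScr against vector, 1535 for the knockdown effect minus the 1K effect and 3575 minus the 2K effect. Leave-outs gave 348 to 696 genes in 1K, 6133 to 7013 in 2K, 3715 to 3943 in the knockdown, 5158 to 5716 for 2K against 1K, 7361 to 8434 for shScr against vector, and 2611 to 3956 and 5044 to 6201 for the differences. The 3715 and 2611 were without shScr replicate 1.

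At an adjusted p below 0.01, which calls fewer genes, 1K and 2K shared 77 higher and 39 lower genes, 1K and the knockdown 20 and 13, and 2K and the knockdown 684 and 447. Among genes at a mean CPM of at least 10, r was 0.423 for 1K and 2K, -0.104 for 1K and the knockdown and -0.0481 for 2K and the knockdown. The cause was not tested.

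Against the other control line, 51 named gene results kept their call, 13 lost it and 37 reversed sign, called or not. The reversed log2 fold changes in 1K were ZNF568 -0.44, ZNF888 -0.14, SIM1 -2.28, KIT -1.38, KLK5 1.47, COLEC10 1.48, MMP13 7.51, RASGRP1 1.14, KLK6 0.92, PMP22 -0.57, RAMP3 -2.43 and AGR3 -1.82. In 2K they were ZNF568 -0.28, RAMP3 -0.14, SHH -0.32, MMP13 3.23, ANXA8 0.49, PMP22 -0.15, SIM1 -1.96 and AGR3 -0.71. In the knockdown they were ZNF568 0.16, IL20 -0.37, AFAP1L2 -0.84, ATP8A2 -1.41, MGP -0.32, TP63 -2.10, AREG -1.24, NIBAN1 0.0096, ACTG2 0.11, KLF2 0.39, TAS1R3 -0.092, SULF1 0.67, SIM1 2.18, COLEC10 -1.39, MMP13 -4.29, RAMP3 2.51 and AGR3 1.17. The MMP13 values in 1K and 2K rest on 1 count in shScr. With both control lines exchanged, 10400 genes were called for the knockdown effect minus the 1K effect and 9825 minus the 2K effect. Of 20 named differences 3 kept their call, 1 lost it and 16 reversed. Those from the 1K effect were MMP13 -11.80, DIO2 -0.17, IL20 -4.65, ATP8A2 -5.58, GJA1 -3.62, PTPRN2 1.15, C9orf152 1.55, BRINP2 6.33, MPPED2 1.64, and those from the 2K effect MMP13 -7.52, SERPINE1 -2.67, TP63 -2.96, RAMP3 2.65, SHH 2.51, AGR3 1.88 and ZNF90 0.068. These reversals follow from the control difference, whose cause was not tested.

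For lists, 76 of 115 results kept their side of the threshold with an estimated correlation and 39 lost the call. With fry 92 kept it, 18 gained a call and 5 lost it, with the replicate block 112 kept it and 3 gained a call, and RLE kept all 115. Of 55 counts of 1 or 2 list members called, 40 changed in at least 1 leave-out.

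The replicate numbers were tried as a block. Deviations of paired replicates correlated at -0.0752 to 0.0665 over 10 pairs of groups.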

Other observations

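The counts and the gene below were chosen after their values were seen.

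Of 297 genes called higher in 1K with a known position, 89 lay on chromosome 19, or 30% against 6.84% of tested genes (odds ratio 6.18, Fisher's exact test, two-sided p = 3.99e-34). Without the KRAB list 45 of 250 did, or 18% against 6.02% (odds ratio 3.53, exact p = 3.17e-11). In 2K, 453 of 4202 did (10.8%, odds ratio 1.99, exact p = 9.73e-28), or 7.93% without it (odds ratio 1.49, exact p = 2.23e-08). In shScr against vector, 484 of 4561 did (10.6%, odds ratio 1.99, exact p = 2.14e-28), or 8.52% without it (odds ratio 1.69, exact p = 1.1e-14). In 2K against 1K, 301 of 3483 did (8.64%, odds ratio 1.38, exact p = 5.6e-06), or 5.63% without it (odds ratio 0.917, exact p = 0.315). In the knockdown, 192 of 3095 did (6.2%, odds ratio 0.883, exact p = 0.129), or 5.71% without it (odds ratio 0.935, exact p = 0.454). Neighbouring genes are not independent, so p-values describe counts. GC content (rho 0.303 with 1K fold changes) and other zinc fingers were not removed.

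MIR30A (ENSG00000207827.1, chromosome 6, 71403551 to 71403621), a microRNA gene, was at 54.6 and 55.5 CPM in shScr and 21.0 and 19.4 in shTRIM28. It was at 0.0282 CPM in 2K replicate 1 and 0 in the others without shRNA, so shRNA construct reads are not excluded.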
